A study of Homo sapiens with 6 samples.

How the data were processed

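RNA from 3 human melanoma cell lines was measured on oligonucleotide expression arrays: the line WM793, which the labels describe as poorly tumourigenic in nude mice, and its sublines WM793-P1N1 and WM793-P2N1, which they describe as highly tumourigenic there. Each line had 2 samples that the labels call biological replicates, so there were 6 arrays in all. Samples were placed in groups by their titles and numbered as the titles number them.

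The deposited values are intensities, 1 linear number for each of 7129 probe sets on each array, and 20.7 to 21.5% of those on an array are below 0. The authors' software, its version and its settings are not given in the sources used here. The 2% trimmed means of the 6 columns differed by at most 0.0623% around 973, which shows that the deposited intensities had already been scaled to a common mean, so they were used as deposited, under a rule set before the data were examined that asked for quantile normalization only if those means differed by more than 5%. An intensity has no unit and sets levels of 1 probe set side by side between arrays, not levels of different genes. Column medians ran from 160.9 to 222.5. No 2 arrays shared more than 5 identical values at the same probe set, so none was a copy of another.

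Control probe sets (58) were left out. A probe set was kept when its value exceeded 97.3, the 40th percentile of the table, in at least 2 of the 6 samples, which left 4663. Negative values were set to 0 and log2(value + 17.4) was taken, where 17.4 is the table's 25th percentile. This offset shrinks the changes of dim probe sets. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) to all 6 samples at once, with 3 residual degrees of freedom and a prior of 4.35. The 4 contrasts were the mean of both sublines against WM793, each subline against WM793, and WM793-P2N1 against WM793-P1N1. P-values were adjusted by Benjamini-Hochberg over the 4663 probe sets of a contrast, with a threshold of 0.05, and every adjusted p of a gene given here is from limma. With 2 arrays per line, the number of arrays limits the precision, and a group mean ± SD has n = 2 throughout.

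Fold sizes were computed from the geometric means of the signals after values below 97.3 had been raised to it. Where a line on the dimmer side lay below 97.3 on both of its arrays, the fold is a bound and is written "at least". The fitted log2 change of such a gene depends on the offset and is no bound.

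Gene names came from the platform annotation supplied for the value table: 5709 probe sets had 1 gene symbol, 321 had several and 1099 had none. Of the first, 5704 were updated by gene ID to the symbols of the RefSeq table for GRCh38.p14. Among the kept probe sets 3871 had 1 symbol, for 3578 genes, of which 260 had several kept probe sets. No gene was named from a probe set with several symbols. The files name no genome build, so no coordinates are given and that table served only for names and for which genes neighbour each other.

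The genes named in the text followed a rule set before the data were examined. For each contrast it took, among probe sets past the threshold with 1 symbol and with no overlap between the groups' values, 1 per gene, the 10 largest rises and the 10 largest falls, leaving out X-inactivation and Y-linked genes. They were ranked by fitted log2 change, which depends on the offset for genes at the floor. Where fewer than 5 passed, it took the 10 smallest p instead, given as values. From each gene list described it took up to 4 members past the threshold with the largest changes, or, where none passed, the member with the smallest p, given as a value.

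Gene lists (28), fixed before the data were examined, were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 28 lists of a contrast, on the brightest kept probe set of each gene. The same test with an estimated correlation stands beside it. Members were also counted after adjustment over the list alone.

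The replicate numbers in the titles were checked for pairing. Deviations of same-numbered samples from their lines' means correlated at 0.37 between WM793 and WM793-P1N1, 0.36 between WM793 and WM793-P2N1 and 0.41 between the sublines, across the kept probe sets, and the second principal component, with 31.2% of the variance, separated the numbers. All 3 values exceed 0.1, so the numbers pair the samples, and the value with the replicate number as a block is given where it changed the call of a named gene or list, or moved a printed count past the adjusted threshold by more than 1.5 times. Log2 values of same-numbered subline arrays correlated at 0.941 and 0.953, against 0.919 and 0.912 between replicates of a subline. Between the sublines, arrays thus resembled each other more by number than by line. The WM793 replicates correlated at 0.909. With same-numbered subline arrays, WM793 replicate 1 correlated at 0.875 and 0.885, and replicate 2 at 0.920 and 0.910.

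Because both sublines were compared with the same WM793 samples, 100 simulated sets of unchanged sublines against those controls gave the overlap and correlation that arise without any effect. The controls could not be split into parts of at least 2 samples. Differences between single arrays that share no sample were correlated instead.

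The fit was tested on simulated data: 200 of 4663 probe sets were changed by known amounts, with each probe set's own mean and spread, in 20 draws. For the mean of both sublines it recovered 28.2% of changes of 1 on the log2 scale, 69.3% of changes of 2 and 83.4% of changes of 4, and 4.79% of calls were false. For WM793-P1N1 alone the shares were 18.4%, 64.2% and 88.9%, with 5.64% false calls. Of lists of 25 probe sets shifted by 1 on the log2 scale in both sublines, camera found 100% with the preset and 88% with an estimated correlation. It called 0.105% and 0% of unshifted lists. The simulated noise was independent between probe sets, so these shares give no false-call rate for lists whose members vary together. In the interferon list, for example, the estimated correlation was 0.22.

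Alternatives set before the data were examined varied the filter, the offset, the normalization, the variance prior, the samples in the fit, the replicate block and the threshold, and left out each sample in turn. Offsets of 100 and 500, cyclic loess, and the block combined with quantile normalization or with the 50th percentile offset were added after seeing the data. Figures were drawn with matplotlib 3.10.9.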

Results

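Expression was profiled in WM793, a human melanoma cell line that forms tumours poorly in nude mice, and in 2 sublines derived from it, WM793-P1N1 and WM793-P2N1, that are highly tumourigenic there. Each line was represented by 2 arrays from biological replicates, and 4663 of 7129 probe sets were bright enough to test. Signals are probe-set intensities scaled to a common mean, and values are mean ± SD (n = 2).

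The first comparison asked which transcripts differ between the highly tumourigenic sublines and the poorly tumourigenic parent. AKR1C3, an aldo-keto reductase that converts steroids and prostaglandins, rose 25.1-fold, from 101 ± 36.9 in WM793, where 1 of 2 arrays was above the floor of 97.3, to 2614 ± 466 in WM793-P1N1 and 3171 ± 1382 in WM793-P2N1 (limma, adjusted p = 0.00146). CRYBG1, first described as a gene absent in melanoma, rose 11.01-fold from 178 ± 4.17 to 2016 ± 216 and 1916 ± 121 (adjusted p = 0.000686). CYBA, a membrane subunit of the NADPH oxidase, fell at least 61.8-fold, from 6287 ± 2593 to below the floor on all 4 subline arrays (adjusted p = 0.000686). CDKN2A, which encodes inhibitors of the cell cycle, fell 29.9-fold from 6642 ± 3772 (9309 in replicate 1 and 3974 in replicate 2) to 206 ± 20.7 and 213 ± 95.04 (adjusted p = 0.00329).

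Among the other rises, MDK, the heparin-binding growth factor midkine, was below the floor in WM793 and reached 469 ± 154 in WM793-P1N1 and 368 ± 128 in WM793-P2N1, a rise of at least 4.15-fold. TGFA, a ligand of the epidermal growth factor receptor, rose 9.05-fold from 148 ± 59.8 to 1707 ± 1085 and 1087 ± 126. IGFBP4, a binding protein of insulin-like growth factors, rose 8.34-fold, and MAGEA4, a cancer-testis antigen above the floor on 1 of 2 WM793 arrays, 8.12-fold. ST6GALNAC2, a sialyltransferase, rose 6.52-fold. RARB, a retinoic acid receptor, rose at least 2.58-fold on 1 probe set, but its other kept probe set had a log2 change of -0.76 with an adjusted p of 0.487. The RARB call ended whichever sample was left out and with no filter. LAPTM5, a lysosomal membrane protein of blood cells, rose at least 2.39-fold and PTPN3, a tyrosine phosphatase, at least 2.28-fold, both from below the floor in WM793. The LAPTM5 and PTPN3 calls each ended in 11 of 18 settings (adjusted p up to 0.176 and 0.195), among them the offsets at the 50th percentile, of 100 and of 500 without the block, cyclic loess and any sample left out.

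MT1E, a metallothionein, fell at least 38.6-fold from 4021 ± 111 to 37.5 ± 69.8 and 45.2 ± 118. BST2, an interferon-induced membrane protein that tethers virions, fell 37.9-fold from 4982 ± 1736 to 140 ± 4.24 and 116 ± 6.58. GPNMB, a glycoprotein of melanosomes, fell at least 30.4-fold, from 5613 and 1842 in WM793 replicates 1 and 2. TYRP1, an enzyme of melanin synthesis, fell at least 18.0-fold, although the WM793 samples themselves differed, with 4398 in replicate 1 and 695 in replicate 2. Its other kept probe set was at least 7.23-fold lower, with an adjusted p of 0.0563 (0.0267 with the replicate block). The TYRP1 call ended whichever sample was left out. It also ended with no filter, a filter at the 60th percentile, eBayes without trend or an offset of 500. IFI6, an interferon-induced gene, fell 14.1-fold, with 1 of 2 WM793-P1N1 arrays above the floor. TNFAIP6, a hyaluronan-binding protein, fell at least 11.9-fold and S100A1, a calcium-binding protein, at least 10.7-fold. MBP, a myelin protein, fell at least 7.52-fold, from 1328 and 403 in WM793 replicates 1 and 2, and its call ended whichever sample was left out (adjusted p up to 0.363).

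In all, 53 probe sets passed the threshold for the mean of both sublines, 28 higher and 25 lower, and 698 had an unadjusted p under 0.05. With the replicate block, 189 passed, 93 higher and 96 lower, and these included all 53. With 1 sample left out the count was between 12 and 22, and of the 20 genes named AKR1C3, CRYBG1, BST2 and CDKN2A stayed past the threshold whichever sample was left out, while the other 16 missed it at least once, with adjusted p up to 0.363. Without the filter on dim probe sets 9 passed, and of these 20 genes BST2, CRYBG1 and CYBA were still among them.

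**Figure D1:**
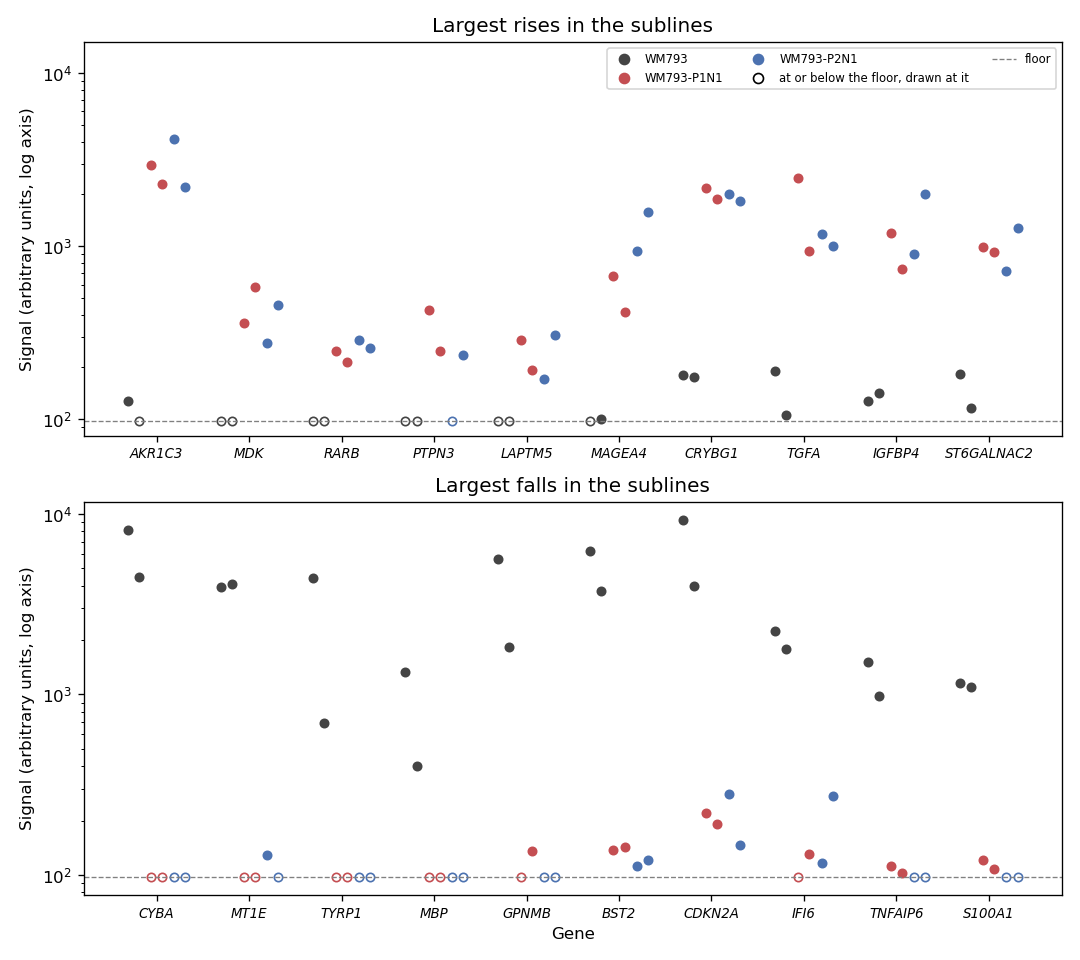
Signal of the 20 genes named by rule for the mean of both sublines. They are the 10 largest rises and 10 largest falls by fitted log2 change among passing probe sets with 1 symbol. The log axis is in arbitrary units, with 1 point per array and the 2 replicates of a line side by side. Probe sets without a single symbol are not drawn, among them 1 that fell at least 233-fold (log2 change -9.23). Open points lie at or below the floor of 97.3 (dashed line) and are drawn at it; CYBA, TYRP1 and MBP are at the floor on all 4 subline arrays, and MDK, RARB, PTPN3 and LAPTM5 on both WM793 arrays.

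By gene list, the interferon response was lower. Of its 27 measured members 4 fell, 0 rose and 23 did not pass, and 10 fell when adjusted over the list alone. With the replicate block 8 were lower, and over the list alone 14 lower and 1 higher. BST2 and IFI6 fell as above, MX1, an antiviral GTPase, fell 5.63-fold from 1382 ± 436 to 236 ± 20.7 and 256 ± 112, and IRF9, a transcription factor of the interferon pathway, fell 2.74-fold. The list's median log2 change was -0.94, or -0.71 with values raised to the floor (camera, adjusted p = 1.1e-07 with the preset and adjusted p = 0.718 with an estimated correlation). Without WM793 replicate 1 the median was -0.57. The MX1 and IRF9 calls ended whichever sample was left out (adjusted p up to 0.205 and 0.226), and the IRF9 call also under quantile normalization and median centring.

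The pigmentation list fell too. Of its 13 measured members, TYRP1 and GPNMB fell and 11 did not pass (3 lower passed with the block), while over the list alone 5 fell and 1 rose. Its median log2 change was -0.90, or -0.72 with values raised to the floor (adjusted p = 0.00808, and adjusted p = 0.718 with an estimated correlation). Without WM793 replicate 1 the median was -0.32 and the call ended (adjusted p = 0.257), as it did with no filter (0.0904).

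Genes of the cell cycle and DNA replication were higher as a list. None of the 36 measured members passed limma's threshold alone, over all probe sets (0) or over the list alone (0), while 12 were higher and 1 lower at an unadjusted p under 0.05. With the replicate block 0 passed over all probe sets, and 11 higher and 1 lower over the list alone. The fitted change was above 0 for 31 of them, with a median of 0.42 (adjusted p = 7.4e-05, and adjusted p = 0.718 with an estimated correlation). CDK1, the mitotic kinase, had 834 ± 49.99 in WM793 against 1709 ± 560 and 1752 ± 247 (adjusted p = 0.125).

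The list of the invasive or dedifferentiated melanoma state was lower, with a median log2 change of -0.62 over 20 measured members (adjusted p = 0.0175, and adjusted p = 0.718 with an estimated correlation). On the probe sets used for the list 1 member passed, higher: TGFBI, a matrix protein induced by TGF-beta, rose 2.36-fold from 4090 ± 307 to 11348 ± 439 and 8326 ± 2122. IL6 passed, lower, on its other probe set (log2 change -2.95, adjusted p = 0.0469), and over the list alone 4 members fell and 1 rose. With the replicate block 6 members were lower and 1 higher, and over the list alone 10 lower and 1 higher. The TGFBI call ended whichever sample was left out (adjusted p up to 0.226). The list call ended with no filter (adjusted p = 0.128) and without WM793 replicate 2 (0.34), WM793-P1N1 replicate 1 (0.0862) or WM793-P2N1 replicate 1 (0.0765).

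For 4 further lists the call ended with the replicate block, and it was lost in 12 (NF-kB), 9 (proteases), 10 (S100 and annexin) and 13 (MHC class II) of 20 settings. NF-kB targets and inflammatory cytokines had a median log2 change of -0.36 (adjusted p = 0.0355, and 0.0535 with the block). In it TNFAIP6 fell, IL1B, an inflammatory cytokine, rose 4.45-fold from 4049 ± 749 to 19033 ± 2655 and 16892 ± 1842, and 21 of 23 members did not pass on the probe sets used, while adjusted over the list alone 1 rose and 4 fell, as with the block over all probe sets. Proteases and their inhibitors had a median of -0.24 (adjusted p = 0.0285, and 0.0535 with the block), and limma passed 0 of 24 members, with 2 higher and 5 lower at an unadjusted p under 0.05, and 5 lower adjusted over the list alone. With the block 2 lower passed, and 2 higher and 5 lower over the list alone. Its member with the smallest p, CSTB, a cathepsin inhibitor, had a log2 change of -0.84 (adjusted p = 0.0813, and 0.0362 with the block). The S100 and annexin list had a median of -0.20 (adjusted p = 0.0326, and 0.0535 with the block), and of 18 members S100A1 passed, lower, while 3 were lower adjusted over the list alone (6 with the block). MHC class II antigen presentation had a median of 0.19 (adjusted p = 0.0486, and 0.0691 with the block), and limma passed 0 of 13 members, with 5 higher and 0 lower at an unadjusted p under 0.05, and 2 higher adjusted over the list alone (with the block 2 and 5). Its member with the smallest p, CD74, the invariant chain, had 3600 ± 466 in WM793 against 9079 ± 213 and 9497 ± 3530 (adjusted p = 0.0571, and 0.0177 with the block). With an estimated correlation none of these 4 passed (adjusted p = 0.718 for each).

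**Figure D2:**
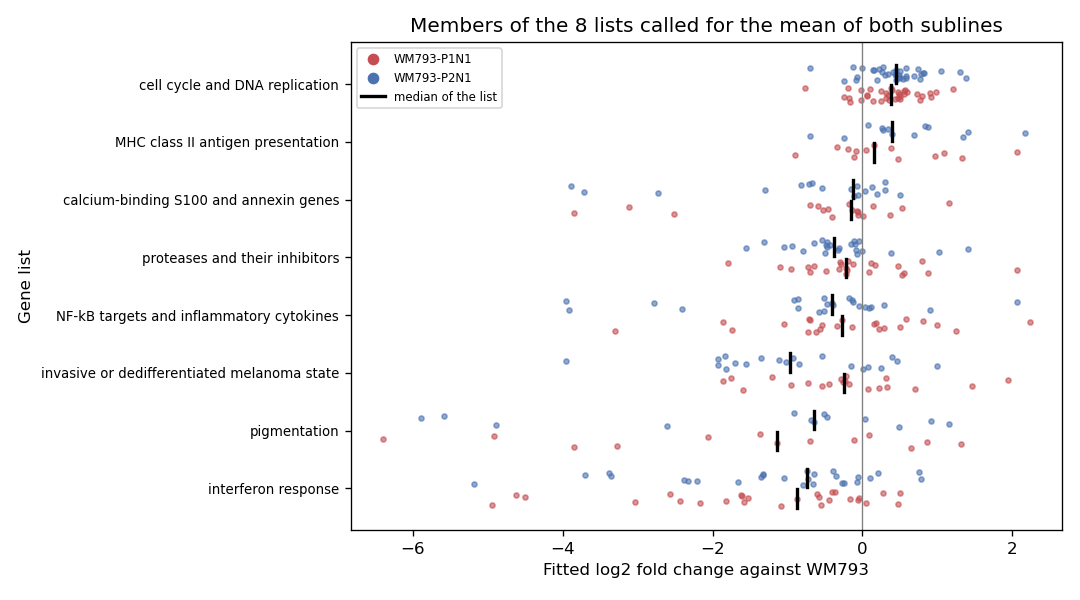
Fitted log2 fold changes against WM793 of the measured members of the 8 lists called for the mean of both sublines, with red points for WM793-P1N1, blue points for WM793-P2N1 and black bars for the medians. The interferon response bars lie at -0.87 and -0.74, the cell cycle bars at 0.38 and 0.45, and changes of genes at the floor depend on the offset.

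Markers of other cell types were measured as a check of the cultures. Of 11 leukocyte markers LAPTM5 rose and 10 did not pass, and the list's median was -0.28 (adjusted p = 0.57). Limma passed 0 of 8 stromal fibroblast markers, 0 of 5 endothelial and 0 of 11 keratinocyte and epithelial markers, with 3, 1 and 1 past an unadjusted p of 0.05, and the adjusted p of these lists were 0.588, 0.466 and 0.96. Their members with the smallest p were LUM, at 247 ± 104 in WM793 and below the floor in both sublines (adjusted p = 0.168), ENG, with a log2 change of -1.13 (adjusted p = 0.0808, and 0.022 with the replicate block), and KRT18, at 320 ± 75.02 in WM793 and below the floor on average in both sublines (adjusted p = 0.0987, and 0.0344 with the block).

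WM793-P1N1 was then compared with WM793 alone. MDK, AKR1C3, CRYBG1, NPTX2 and IL1B rose. NPTX2, a secreted pentraxin of synapses, went from 1322 ± 135 to 7404 ± 862, a 5.60-fold rise (adjusted p = 0.00909), and IL1B rose 4.72-fold. CYBA, BST2, GPNMB, CDKN2A, IFI6, TNFAIP6 and S100A1 fell, by at least 61.8-fold for CYBA and by 34.5-, 27.9-, 29.6-, 17.7-, 11.3- and 9.81-fold for the others, where GPNMB and IFI6 were above the floor on 1 of 2 WM793-P1N1 arrays. These 12 genes were all that passed with 1 symbol. The interferon response (median log2 change -0.87, adjusted p = 3.9e-08) and pigmentation (-1.14, adjusted p = 0.00388) were lower and the cell cycle list higher (0.38, adjusted p = 0.00116), each with an adjusted p of 0.797 with an estimated correlation. By limma 13 probe sets passed, 5 higher and 8 lower, 579 had an unadjusted p under 0.05, and with the replicate block 80 passed, 39 higher and 41 lower. With 1 sample left out the count was between 4 and 18 and 10 of the 12 genes missed the threshold at least once, without WM793 replicate 1 the pigmentation and cell cycle calls ended (adjusted p = 0.162 and 0.0759), the pigmentation call also with no filter (0.0634), and after cyclic loess the split was 8 higher and 8 lower.

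In WM793-P2N1 against WM793 the rises were AKR1C3 (27.1-fold), MDK (at least 3.67-fold), MAGEA4 (12.3-fold), RARB (at least 2.81-fold on 1 probe set, with a log2 change of -1.13 and an adjusted p of 0.48 on the other), CRYBG1 (10.8-fold), IGFBP4 (9.97-fold), NPTX2 (6.02-fold), ST6GALNAC2 (6.55-fold), IL1B (4.20-fold) and ETV4 (2.65-fold), a transcription factor downstream of MAPK signalling. The falls included CRHR1, the receptor of corticotropin-releasing hormone, from 959 ± 70.6 to below the floor, at least 9.84-fold (adjusted p = 0.0014). IL6, an inflammatory cytokine, fell at least 14.6-fold from 1476 ± 590 on 1 of its 2 kept probe sets, and the other had a log2 change of -3.96 with an adjusted p of 0.0554 (0.00267 with the replicate block). TAC1, the precursor of substance P, fell 16.8-fold from 3193 ± 32.9 to 208 ± 120 on 1 probe set, and its other was 10.8-fold lower with an adjusted p of 0.0772 (0.0131 with the replicate block). CHN1, a Rac GTPase-activating protein, fell 2.88-fold. The MDK, RARB, ST6GALNAC2, ETV4 and CHN1 calls ended whichever sample was left out. CYBA, GPNMB, BST2, CDKN2A, TNFAIP6 and S100A1 fell, by at least 61.8-, 33.0-, 12.5- and 11.6-fold for CYBA, GPNMB, TNFAIP6 and S100A1 and by 41.7- and 30.1-fold for BST2 and CDKN2A.

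In the same comparison the interferon response (median log2 change -0.74, adjusted p = 4.4e-07), the invasive state (-0.97, adjusted p = 0.000381), NF-kB targets (-0.40, adjusted p = 0.00251), proteases (-0.38, adjusted p = 0.00425), pigmentation (-0.65, adjusted p = 0.0091) and the S100 and annexin list (-0.13, adjusted p = 0.0224) were lower. The cell cycle list (0.45, adjusted p = 2.9e-05) and MHC class II presentation (0.39, adjusted p = 0.0091) were higher. With an estimated correlation each had an adjusted p of 0.586. By limma 22 probe sets passed, 10 higher and 12 lower, 539 had an unadjusted p under 0.05, and with the replicate block 99 passed, 48 higher and 51 lower. With 1 sample left out the count was between 7 and 22 and 16 of the 20 genes named missed the threshold at least once, and the pigmentation call ended with no filter (adjusted p = 0.136) and without WM793 replicate 1 (0.442) or WM793-P2N1 replicate 1 (0.0721). The MHC class II and the S100 and annexin calls ended without WM793 replicate 2 (adjusted p = 0.18 and 0.416), and each in further settings. Without WM793-P2N1 replicate 2 the S100 and annexin median was 0.05, where camera still placed the list lower (adjusted p = 0.016).

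The sublines resembled each other in what had changed. Of the 13 and 22 probe sets called in them, 12 were called in both in the same direction, 5 higher and 7 lower, and 0 in opposite directions, also at an unadjusted p under 0.05 (0 by limma). Sets simulated without any effect also held 0 calls in opposite directions past the adjusted threshold, so that 0 is no sign of likeness. The 12 include AKR1C3, MDK, CRYBG1, NPTX2 and IL1B among the rises and CYBA, BST2, GPNMB, CDKN2A, TNFAIP6 and S100A1 among the falls. Sets simulated without any effect, with the WM793 samples drawn too, shared 0.07 calls on average and at most 1. Independent lists of these sizes would share 0.0107 rises and 0.0206 falls. With the replicate block 62 were shared, against 0.15 on average and at most 2 in simulated sets fitted with the block. Sets without any effect hold few calls in either subline, because the adjustment keeps them few, and independent lists ignore the shared WM793 samples. Neither reference therefore tests whether lists of 13 and 22 calls overlap beyond what the shared samples give. Across probe sets, which are not independent replicates, the fold changes of the sublines correlated at 0.81, against 0.50 in the simulation, and their covariance was 0.57 against 0.17, a difference of 0.41. The simulated values already include the sharing of the WM793 samples at the fitted spread. Part of the excess may thus come from that sharing only if these samples varied more than fitted. Single-array differences that share no sample correlated at 0.42 (WM793-P1N1 replicate 1 less WM793 replicate 1, and WM793-P2N1 replicate 2 less WM793 replicate 2) and 0.44 (the other numbers). Sharing of samples cannot give these correlations, which argue against it as the whole source of the likeness.

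The direct comparison asked where the sublines differ. CRHR1 was the probe set that passed: it had 616 ± 75.5 in WM793-P1N1 and was below the floor in WM793-P2N1, at least 6.31-fold lower (log2 change -5.18 ± 0.39 SE, adjusted p = 0.00945). Below the threshold, the smallest p belonged to SERPINA5, a protease inhibitor, with -33.6 ± 44.6 in WM793-P1N1 and 537 ± 314 in WM793-P2N1, FGFR1, a growth factor receptor, with 3291 ± 402 and 1649 ± 11.1, and MST1R, a receptor tyrosine kinase, with 530 ± 53.4 and 134 ± 82.8. VIPR1, a neuropeptide receptor, had 1884 ± 142 and 122 ± 272, and KYNU, an enzyme of tryptophan breakdown, had 2409 ± 599 and 1207 ± 217. Each of these 5 had an adjusted p of 1.

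Between the sublines 4 lists differed. The invasive state was lower in WM793-P2N1, with a median log2 difference of -0.46 and 17 of 20 members lower (adjusted p = 7.9e-07). NF-kB targets were lower, with -0.32 and 18 of 23 members lower (adjusted p = 6.3e-05), as was MAPK pathway output, with -0.25 and 13 of 19 (adjusted p = 0.0199). Cholesterol and fatty acid synthesis was higher, with 0.20 and 10 of 14 members higher (adjusted p = 0.0178). The members with the smallest p were IL6 in the first 2 lists, with 943 ± 771 against 175 ± 78.0, FOSL1, a transcription factor of the AP-1 family, with 240 ± 54.0 against a level below the floor, and MVD, an enzyme of sterol synthesis, with 189 ± 16.6 against 356 ± 6.93 (adjusted p = 1 for each). By limma 0 members of these lists passed, with 4, 3, 2 and 2 past an unadjusted p of 0.05. With an estimated correlation the lists had adjusted p = 0.544, 0.544, 0.544 and 0.557.

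By limma 1 probe set passed between the sublines, with and without the replicate block, and 68 had an unadjusted p under 0.05 (187 with the block). All 4 list calls ended without WM793-P1N1 replicate 2 (adjusted p = 0.127, 0.47, 0.5 and 0.5), the invasive state and MAPK output also without WM793-P2N1 replicate 1 (0.0557 and 0.232), cholesterol synthesis without WM793-P2N1 replicate 2 (0.928, median -0.02) and MAPK output with no or a stricter filter, and the CRHR1 call ended with an offset at the 50th percentile (adjusted p = 0.0923) or of 500 (0.371), with a stricter or no filter, with only the sublines fitted, or with any sample left out except WM793-P2N1 replicate 2.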

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

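Both tests on the interferon list, the test on the quality of the labelled RNA and those of genes and lists between replicate numbers were chosen only after the results were seen.

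The sublines differed from each other at CRHR1, a call that ended with an offset at the 50th percentile, with a stricter or no filter, and with only the sublines fitted. WM793-P2N1 was at least 6.31-fold lower than WM793-P1N1, with a log2 change of -5.18 that depends on the offset. Lists that differed between them were the invasive or dedifferentiated melanoma state, at a median of -0.46, NF-kB targets and inflammatory cytokines, at -0.32, MAPK pathway output, at -0.25, and cholesterol and fatty acid synthesis, at 0.20, with adjusted p = 0.544, 0.544, 0.544 and 0.557 with an estimated correlation, so none of these 4 calls held there. Each is a direct test of the difference, and none of the list calls held without WM793-P1N1 replicate 2 (adjusted p = 0.127, 0.47, 0.5 and 0.5). The invasive state and MAPK output also lost theirs without WM793-P2N1 replicate 1 (0.0557 and 0.232), and cholesterol synthesis without WM793-P2N1 replicate 2 (0.928).

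The lower interferon-response list in the sublines was weighed against 2 technical explanations. Its call did not hold with an estimated correlation between genes (camera, adjusted p = 0.718). The brightest signals were higher on the WM793 arrays, where the 99th percentiles were 24150 and 21688, than on all 4 subline arrays, where the highest was 21246. Under quantile normalization, which removes that difference, the list's median stayed at -0.91, against -0.94 as deposited (95% bootstrap interval over members -1.51 to -0.41). So small a move of the median argues against that difference as the whole cause. A single WM793 culture with high interferon genes would need the change to vanish without WM793 replicate 1. There the median was -0.57, with an interval of -1.11 to -0.00256. Part of the change thus rests on that sample, and the upper end lies close to 0. Both intervals give the spread among members that vary together on the same arrays (estimated correlation 0.22). They do not measure the spread between cultures of a line. A difference between the lines in interferon signalling stays open, as does a shared state of the 2 WM793 cultures, which may differ from that of the sublines for reasons the design does not separate.

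Samples with the same replicate number deviated together in every pair of lines. Between replicate numbers 99 probe sets passed limma's threshold with lines as a factor, 70 higher and 29 lower in replicate 1; by camera the invasive state was lower there (median -0.34, adjusted p = 0.000434, with -0.37, -0.44 and -0.39 in the 3 lines), as was the cell cycle list (-0.14, adjusted p = 0.0497), stromal markers were higher (0.75, adjusted p = 0.0497), and each had adjusted p = 0.925 with an estimated correlation. Background of dim probe sets alone would leave the bright ones uncorrelated. In the brightest 933 the deviation correlations ran from 0.35 to 0.41, with the lowest at 0.346. This argues against background as the whole source, but a correlation does not register a shift in level. The median of replicate 1 less replicate 2 was 0.37 in the dimmest 933 probe sets and -0.05 in the brightest 933. Background thus stays open as part of the source among dim probe sets. Whether that shift in level adds to the 70 higher calls or to the stromal list was not tested. The ACTB 3'/5' ratio was higher in replicate 1 in all 3 lines and the GAPDH ratio in 1, so quality of the labelled RNA cannot be told apart from any other factor shared by a number. A shared culture or processing day may also be the source, and no biological explanation was tested.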

How the results depend on the processing

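Of 199 results recomputed under 24 settings, no called gene changed sign and camera turned no called list. Without WM793-P2N1 replicate 2, the medians of 2 called lists crossed 0, S100 and annexin in WM793-P2N1 (from -0.13 to 0.05) and cholesterol synthesis between the sublines (from 0.20 to -0.02). Offsets of 100 and 500, cyclic loess, and the replicate block combined with quantile normalization or the 50th percentile offset were chosen after seeing the data. The 10th percentile offset was not run, since that percentile is -73.07, and camera has no robust setting. The counts below are for the mean of both sublines, WM793-P1N1, WM793-P2N1, WM793-P2N1 against WM793-P1N1, and both sublines the same way, where the main counts were 53, 13, 22, 1 and 12. With no filter on dim probe sets they were 9, 4, 10, 0 and 4, and with adjusted p 0.01 they were 13, 8, 8, 1 and 7. With the replicate block, which pairs the samples, they were 189, 80, 99, 1 and 62, with quantile normalization and the replicate block 199, 71, 91, 1 and 57, and with the 50th percentile offset and the replicate block 277, 122, 153, 1 and 89. eBayes without trend gave 29 for the mean of both sublines. The single probe set between the sublines was lost (0) with the filter at the 60th percentile, the offset at the 50th percentile, the offset of 500 and only the groups compared. The offset of 500 gave splits of 17 higher and 28 lower, 4 and 11, and 6 and 22 for the first 3 counts. With 1 sample left out, a lone sample being assumed to vary like the other groups, the counts ran from 12 to 22, 4 to 18, 7 to 22, 0 to 2 and 4 to 9. The other settings kept each count within 1.5 times. Apart from the cause that fewer samples or a stricter threshold give by construction, the cause was not tested. Of 58 calls of named genes, 6 held under every setting run: CRYBG1 in the 3 comparisons with WM793, BST2 in the mean of both sublines and in WM793-P2N1, and CRHR1 in WM793-P2N1. The replicate block ended no named gene's call and added 7, for MGP, CSTB, ITGA6, CD74, ENO2, ENG and KRT18. It brought other probe sets of TYRP1, IL6 and TAC1 past the threshold too, and ended 4 of 23 list calls; an estimated correlation ended all 23. Of the lists called for both sublines, the interferon response and cell cycle calls held under the other 19 settings, with medians from -1.33 to -0.41 and from 0.32 to 0.51. Of the values on an array 20.7 to 21.5% lie below 0, so signal over background limits the folds of dim genes.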

Other observations

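The tests of the run of neighbouring genes, its window sizes and the genes beside CDKN2A were chosen only after the results were seen. Several lists fixed before the data were examined were not called for the mean of both sublines, but held single genes that changed. CDKN2A fell within p53 targets and CDK inhibitors, where 11 of 12 members did not pass (1 higher and 2 lower passed with the replicate block), and MDK rose within angiogenesis factors, where 15 of 16 did not (1 higher and 1 lower passed with the block). ETV4 rose 2.58-fold, from 1374 ± 30.3 to 3460 ± 35.5 and 3640 ± 270, within MAPK pathway output, and the other 18 members did not pass. The ETV4 call ended whichever sample was left out (adjusted p from 0.0579 to 0.118) and with eBayes without trend. TGFA rose within receptor tyrosine kinases and ligands, where 19 of 20 did not pass, and MAGEA4 within the cancer-testis antigens, where 5 of 6 did not (1 higher and 2 lower passed with the block). In the neural crest and Schwann-like list MBP and S100A1 fell and 10 of 12 members did not pass.

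Other lists had no called member. In hypoxia and glycolysis limma passed 0 of 25, and ENO2, the neuronal enolase, had 242 ± 58.9 in WM793 against 715 ± 70.1 and 657 ± 160 (adjusted p = 0.0794, and 0.0344 with the replicate block). In the extracellular matrix list limma passed 0 of 22, and MGP, the matrix Gla protein, had 856 ± 156 against 3155 ± 1288 and 3573 ± 2592 (adjusted p = 0.129, and 0.0177 with the replicate block). Among integrins, cadherins and other adhesion genes limma passed 0 of 25, and ITGA6 had 3355 ± 310 against 7057 ± 990 and 5889 ± 1075 (adjusted p = 0.0893, and 0.0454 with the replicate block). Oxidative phosphorylation had a median log2 change of 0.09 over 31 members (adjusted p = 0.57).

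CDKN2B, the neighbour of CDKN2A on chromosome 9, had 304 ± 126 in WM793 and 26.8 ± 38.6 and 40.3 ± 22.8 in the sublines (adjusted p = 0.185). MTAP, the measured gene on the other side, had 112 ± 5.16, 134 ± 6.58 and 149 ± 0.99 (adjusted p = 0.791), near the floor in all 3 lines.

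Measured genes that lie next to each other on chromosome 5, from CCT5 to GHR, were higher in the sublines as a run of 15 genes, with a median log2 change of 1.04, 1.07 in WM793-P1N1 and 1.02 in WM793-P2N1, and 10 of the 15 were higher in both, though none passed the threshold singly. CCT5, a chaperonin subunit, went from 3964 and 6382 in WM793 to between 9325 and 11187, and TARS1, a tRNA synthetase, from 1457 and 1878 to between 3058 and 4065. These were the brightest of the run, and the other genes had mean signals from 95.2 to 630. LIFR, C9 and GHR were below the floor on both WM793 arrays, so their fitted changes depend on the offset. The run was first seen in running medians along the chromosomes. Against chance order, 0 of 1000 shuffles of 3577 genes had a window as large anywhere (permutation p = 0.001, the smallest possible). The largest windows of 10 and 25 genes had other ends, CCT5 to C9 and SRD5A1 to HTR1A on chromosome 5. Their medians were 1.05 and 0.80, with permutation p = 0.04 and 0.001. Noise of dim probe sets is argued against by shuffles among genes of similar mean signal (5 bins), where 0 of 1000 had a window as large (permutation p = 0.001, highest 0.93). All these shuffles move genes on the same arrays, so their p-values measure gene order and not the spread between cultures of a line. A gain of that segment in the sublines, or in the cell they descend from, may be the source, as a hypothesis that no DNA measurement here tests.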
